A study of Mus musculus with 4 samples.

How the data were processed

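RNA of mouse E14 embryonic stem cells was measured on Illumina bead arrays. Per the labels, the cells carried a stably integrated viral shRNA, either a scrambled sequence or one against AKAP95, the protein of the gene Akap8. They were kept on gelatin with LIF, the cytokine that keeps these cells undifferentiated, or were grown for 4 days without LIF and then for 4 days in 1 µM all-trans retinoic acid (RA). Total RNA was made into biotin-labelled cRNA, per the labels. The design crossed shRNA with RA and gave 4 groups of 1 array each, so that no group had a replicate. The group of each array was taken from its title. What is called the RA effect is the difference between these culture conditions, in which RA goes together with the loss of LIF and with time in culture.

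The authors gave, for each of 25697 probes and each array, an average bead signal as a linear intensity without normalization and a detection p-value. Per the file headers these deposited p-values and signals come from the Illumina scanner software, 1 of each per probe and array, and the software's version and any background subtraction are not stated. In a second table the deposited values are a ratio, the intensity of each probe divided by the median of its own array, which is the median normalization that the authors name. Another deposited table repeats the intensity and the ratio and adds the relative expression, which is the ratio over that of the undifferentiated scramble array. The 3 tables were checked against each other, and for all 25697 probes of each array the recomputed values matched to a relative tolerance of 1e-05.

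The non-normalized intensities were taken from there. Background was corrected and the arrays were quantile-normalized together with limma 3.58.1 in R 4.3.3, in the way of its neqc function. The mean and spread of the negative controls were inferred from the detection p-values, because no control probes were among the values used here, and an offset of 16 was added before the log2 step. Gene symbols were brought up to date by matching each probe's RefSeq accession or old symbol to the mouse RefSeq annotation: 23876 probes (92.9%) matched by accession and 7126 took another symbol. The annotation was used for names and chromosomes alone. The probes stood for 18061 genes, 4897 of them with more than 1 probe, and each gene was read from the probe with the highest mean over the 4 arrays. Later steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

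A gene was called detected on an array at a detection p under 0.01, and was compared if detected on at least 1 array of the pair. Where it was detected on 1 side alone, the dim side was raised to the lowest log2 value among the detected probes of that array. The difference is then a bound, written as "at least". It is a bound under the background correction and normalization used, and other settings can give a smaller value. Of the 25697 probes, between 11344 and 12156 were detected per array, and 9956 genes were detected on at least 1 array and 7643 on all 4. The precision of every value is limited by the number of arrays.

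Each of the 4 comparisons was a difference of 1 array against 1 array. No p-value can be had from it, so a fixed size rule was used, a log2 difference of at least 1 in size (2-fold). An additive limma model with RA and shRNA as its terms was fitted over all 4 arrays to the 9956 genes. Its 1 residual degree of freedom holds the noise together with any difference between the effects of RA in the 2 cell populations, and was pooled over genes by empirical Bayes. P-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The crossed contrast, which is the knockdown effect after RA less that before RA, divided by 2, was used as a yardstick, since it holds noise and interaction alone. The spread between probes of 1 gene on the same arrays gave the noise between probes. It does not hold differences that all probes of an array share, nor those between cultures. Genes for the comparison of RA responses were chosen on the mean RA effect of both populations. Correlations across genes carry no p-value, since genes are not independent replicates.

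There were 19 gene lists: the targeted gene and its paralog, MLL/SET1 complexes, pluripotency, retinoic acid response, Hox clusters, neural and neuronal, cell cycle, p53 targets, interferon response, stress and unfolded protein response, hypoxia and glycolysis, imprinted genes, extracellular matrix and housekeeping, and 5 marker lists for other cell types (extraembryonic and definitive endoderm; mesoderm, endothelium and muscle; trophectoderm; germ line; fibroblast). The median of a list was ranked among 10000 random lists of the same size, matched on mean expression in 10 bins, with seed 7. That rank describes these arrays and is not a test between cell populations. The genes named are the 8 with the largest increase and the 8 with the largest decrease in each comparison, the 5 each way for the difference of the RA responses, up to 4 members of each list that differed by at least 2-fold, the 5 each way with the smallest adjusted p, and Akap8 and Akap8l. Unnamed loci were left out of these picks and stayed in all counts, and the sign of a picked gene had to be the same in the deposited median-normalized values. The comparisons, lists, size rule, naming rule and main alternatives were chosen before the data were examined. 7 further gene families (prolactin family, placental cathepsins, Rhox homeobox cluster, histone genes, guanylate-binding proteins, DNA methylation enzymes and meiosis genes) were chosen after the values were seen.

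The alternatives were no background correction, median scaling, cyclic loess, the deposited median-normalized values, an offset of 50, the mean of all probes of a gene, detection p under 0.05, no detection filter, detection on every array compared, measured values without bounds, a 3-fold rule, genes chosen in 1 cell population alone, and limma with a trend or with robust empirical Bayes. The deposited ratios were multiplied by a single constant, the mean of the 4 array medians, so that a floor of 16 could be applied to them in the unit of the signal. A further alternative, chosen after seeing the data, subtracted a share of the undifferentiated knockdown signal from the RA-treated knockdown array. The deposited median-normalized values shifted the median of all genes for the RA effect in knockdown cells to 0.13 on the log2 scale, against 0.02 in the main setting.

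The procedure was tested on simulated data in which 200 probes differed by a known amount, which left 148 changed genes among those tested. limma recovered 92.3% of genes set 1 log2 unit higher and 87.9% of those set 1 unit lower, and all of those set 2 units higher or lower, with 0 false calls among 13229 unchanged genes. The size rule found 23.1% and 39.4% of the genes set 1 unit higher and lower. These lie at its threshold, and their median estimates were 0.92 and -0.96, somewhat smaller than the amount set. Of 12682 unchanged genes compared, 1 passed the size rule. The simulated RA response was equal in both cell populations, and the simulated arrays held technical noise alone. No knockdown effect was simulated, so the recovery of such an effect was not tested.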

Results

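Expression was measured in mouse E14 embryonic stem (ES) cells with scramble or AKAP95 shRNA, undifferentiated or differentiated with RA, on 4 arrays, 1 per group. The number of probes detected, of 25697, was 11348 (44.2%) in undifferentiated scramble cells, 11344 (44.1%) in undifferentiated knockdown cells, 11817 (46.0%) in RA-treated scramble cells and 12156 (47.3%) in RA-treated knockdown cells. The median signal was 75.5, 75.1, 82.8 and 82.0 in the same order. The study is about the MLL2 histone methyltransferase complex and AKAP95, and the comparisons ask how loss of AKAP95 bears on gene expression in ES cells and on their response to RA. With 1 array per group no difference between 2 arrays could be held against a spread between replicates. This holds for all pairwise values given here. The RA-treated cells had also been without LIF, so that every RA effect given here holds the effects of RA, of LIF withdrawal and of time in culture together, which cannot be told apart in this design.

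Akap8, the gene of AKAP95, was lower in the knockdown cells of both states. Its signal was 272 in undifferentiated scramble cells and 139 in undifferentiated knockdown cells, a log2 difference of -1.19 (2.28-fold). After RA it was 297 in scramble and 199.7 in knockdown cells, a log2 difference of -0.77 (1.70-fold). Akap8 lies on chromosome 17 and was read from 1 probe, detected on all 4 arrays. Its paralog Akap8l differed by 0.03 between scramble and knockdown cells in each state, and was higher after RA by 0.69 in both populations. In the additive limma model the knockdown effect on Akap8 was -0.98 (standard error 0.19; adjusted p = 0.817 over all genes, and 0.0163 when adjusted over the list alone of Akap8 and Akap8l). Without background correction the Akap8 differences were -0.93 and -0.60.

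RA treatment of scramble cells gave 1361 genes higher and 1136 genes lower by at least 2-fold, of 9584 compared. A fold given for a single gene as "at least" is a bound under the main background correction and normalization. Other settings can give a smaller value. Among the largest increases were Igfbp5 and Igfbp4, which bind insulin-like growth factors (at least 199.7-fold and 53.4-fold higher), and Nr2f1, an orphan nuclear receptor of the developing brain (at least 126-fold). The anterior-posterior patterning genes Hoxa5 and Hoxb5 were each at least 103-fold higher, and the hormone gene Sst at least 76.7-fold. The imprinted genes Dlk1 and Peg3 were 74.5-fold and at least 51.7-fold higher. The largest decreases were in Dnmt3l, a cofactor of de novo DNA methylation (at least 244-fold lower), in Pou5f1, which encodes the pluripotency factor Oct4 (61.7-fold), and in the amino acid transporter gene Slc7a3 (55.6-fold). Zfp42 and Esrrb, both markers of naive ES cells, were 49.7-fold and 47.0-fold lower, the kinase gene Sgk1 41.5-fold, Fbxo15 38.8-fold and Zscan4c, a gene of the early embryo, 36.1-fold.

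Of the 27 pluripotency genes compared in scramble cells, 26 were lower by at least 2-fold and 0 higher, with a median log2 difference of -4.24, below that of all 10000 random lists. The retinoic acid response list had 14 of 18 members higher and 1 lower (median 3.11). Its highest included the receptor gene Rarb (5.55, a bound) and the Hox cofactor gene Meis1 (5.18). In the Hox clusters 16 of 21 members were higher and 0 lower (median 3.43), with bounds of 5.67 for Hoxd4 and 5.45 for Hoxc6. The neural and neuronal list had 10 of 16 members higher and 1 lower (median 1.57). These included Dbx1, a homeobox gene of neural tube progenitors (at least 20.9-fold), the neurofilament gene Nefm (at least 16.1-fold), Zic1 (at least 7.93-fold) and the migrating-neuron gene Dcx (at least 6.77-fold). Of 14 imprinted genes, 10 were higher and 1 lower (median 2.24), among them Igf2 (4.34) and Mest (3.91). The extracellular matrix list had 9 of 12 higher and 0 lower (median 1.37), such as Dcn (2.58, a bound) and Mmp2 (2.37).

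Among markers of other cell types, the endoderm list had 13 of 24 members higher and 1 lower in scramble cells (median 1.36), including Gata6 (3.47) and Foxa1 (2.67). The fibroblast list had 4 of 6 higher and 1 lower (median 1.83), with Vim at 2.51, Twist1 at 2.23 and Thy1 at -3.04, a bound. The germ line list had 0 of 6 higher and 3 lower (Piwil2 -2.86, Stk31 -2.08, Taf7l -1.30). The mesoderm, endothelium and muscle list had 4 of 10 higher and 2 lower (median 0.10; Gata2 2.72, Pecam1 -3.33), and trophectoderm 1 of 5 higher and 1 lower (Krt7 2.03, Tfap2c -1.93). In the stress list, Trib3 (-3.41, a bound), Chac1 (-2.89) and Asns (-1.94), all targets of the amino acid response, were lower, and Herpud1 higher (1.11), of 10 compared. The cell cycle list had 1 of 17 lower (Ccne1, -1.94), and p53 targets had 1 of 13 higher (Cdkn1a, 1.47) and 2 lower (Gdf15 -1.40, a bound, and Pmaip1 -1.34). Higher members of other lists included Usp18, Oasl2 and Ifit2 of 10 interferon response genes, Vegfa (2.61), P4ha1 (2.37) and Pfkl (1.16) of 13 hypoxia genes, B2m (1.64) of 13 housekeeping genes, and Ncoa6 (1.16) of 11 MLL/SET1 complex genes, where Rbbp5 (-1.35) and Dpy30 (-1.06) were lower. Of the 66 genes named here that were past 2-fold, 10 were below 2-fold under at least 1 alternative setting of the values or probes, among them Rbbp5, Ncoa6, Gdf15, Pmaip1, Oasl2 (0.40 with the mean of all probes), Ifit2, Pfkl and Taf7l, and Trib3 was at -1.61 with the mean of all probes. With the deposited median-normalized values 699 genes were lower by at least 2-fold.

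In AKAP95 knockdown cells, RA gave 1186 genes higher and 946 lower by at least 2-fold, of 9606 compared. Igfbp5 (at least 112-fold), Hoxa5 (at least 99.5-fold), Nr2f1 (at least 64.6-fold), Dlk1 (60.5-fold) and Hoxb5 (at least 57.8-fold) again led the increases. With them stood Stra8, a gatekeeper of meiosis that RA induces in germ cells (at least 46.9-fold), Hoxb2 (at least 35.1-fold) and Peg3 (30.8-fold). The largest decreases were in the protease inhibitor gene Spink1 (52.8-fold), Dnmt3l (48.3-fold), the threonine dehydrogenase gene Tdh (at least 47.1-fold) and Stmn2, a regulator of neuronal microtubules (39.1-fold). Etv4, an ETS factor of FGF signalling (29.3-fold), Tdgf1, a co-receptor for Nodal (at least 28.5-fold), Slc7a3 (27.7-fold) and Utf1 (26.8-fold) were next. The bounds for Tdh and Tdgf1 rest on the background correction. Before it, the Tdh signal was 1753 in undifferentiated and 84.6 in RA-treated knockdown cells. The Tdgf1 signal was 1030 and 81.6 in the same order.

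The pluripotency list had 25 of 27 members lower after RA in knockdown cells and 0 higher, with a median of -3.14. Of 18 retinoic acid response genes, 13 were higher and 1 lower (median 2.41), and of 23 Hox genes, 16 were higher and 0 lower (median 2.71). Of 14 neural and neuronal genes, 3 were higher and 2 lower, with a median of 0.07. Nes (1.42) and Map2 (1.32) were higher, Gap43 (-1.46) and Stmn2 lower. Imprinted genes had 10 of 14 higher and 1 lower (median 1.97), and extracellular matrix 5 of 10 higher and 1 lower (median 1.15). Among the marker lists, 9 of 23 endoderm genes were higher and 2 lower (median 0.71), and 2 of 5 fibroblast genes were higher and 1 lower (median 0.74). Of 7 germ line genes Dazl was higher (2.44) and Piwil2 lower (-1.58). The mesoderm list had 3 of 11 higher and 2 lower (median 0.13), and trophectoderm 1 of 6 higher and 0 lower (Krt7, 2.08). The interferon response list had 4 of 12 higher and 0 lower (Oasl2 3.54, Usp18 2.53, Rsad2 1.35 and Isg15 1.29, all bounds), p53 targets 1 of 13 higher and 3 lower, stress genes 0 of 10 higher and 3 lower, and hypoxia genes 2 of 12 higher and 1 lower (Pdk1, -1.35). The cell cycle list had a median of -0.58 over 17 genes with 1 lower, housekeeping 1 of 12 higher, and MLL/SET1 complexes 0 of 11 higher and 2 lower. Of 60 named genes past 2-fold, 10 were below it under at least 1 alternative setting of the values or probes, among them Map2 (0.49 with the mean of all probes), Gap43, Rsad2 and Isg15, and Oasl2 was at 1.72 with the mean of all probes. Without background correction 627 genes were lower by at least 2-fold, and with the deposited median-normalized values 474, where 70.8% of the genes past 2-fold were higher, against 55.6%.

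**Figure D1:**
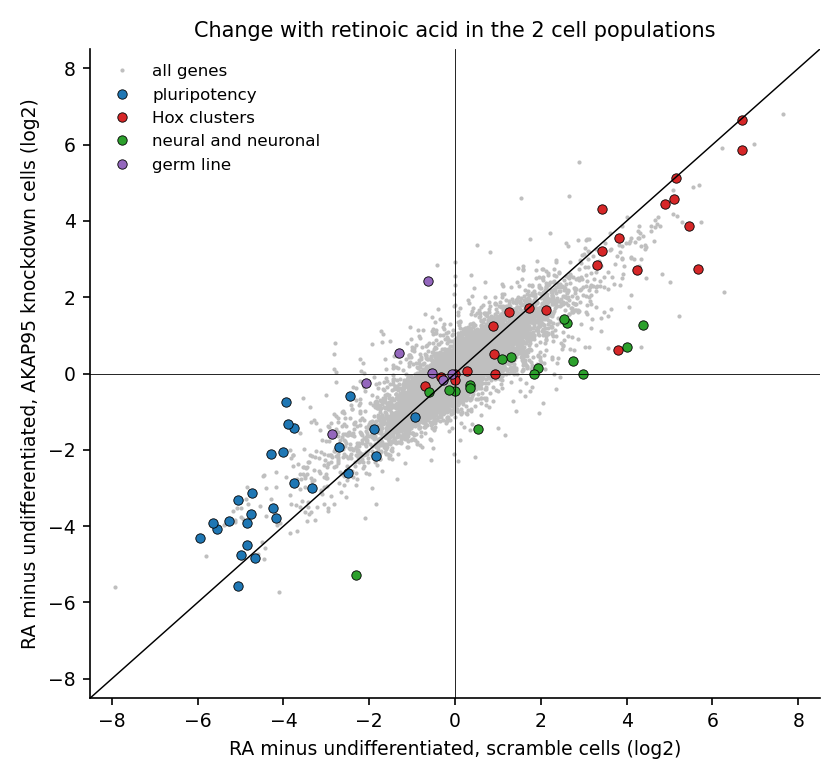
Each point is a gene, with its log2 difference of RA-treated minus undifferentiated cells in scramble cells on the horizontal axis and in AKAP95 knockdown cells on the vertical axis, both with bounds where a side was not detected; colours mark 4 gene lists and the diagonal marks equal differences. The pluripotency median is -4.24 in scramble and -3.14 in knockdown cells, and the neural and neuronal median 1.57 and 0.07.

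Over both populations, limma found 1874 genes that rose and 1627 that fell with RA at an adjusted p under 0.05, of 9956 tested. The smallest adjusted p was 0.00892, shared by Hoxa5 (log2 7.64, standard error 0.16), Dlk1 (6.07), Hoxb2 (5.37), Igfbp5 (7.98) and Hoxb5 (6.80), all higher after RA. At the same adjusted p from limma, Tdh (-5.79), the keratin gene Krt42 (-5.05), the bHLH factor gene Tcf15 (-4.71), the growth factor gene Fgf17 (-4.75) and Utf1 (-4.86) were lower. Each of these had the same direction in both populations. The limma fit used values without bounds. Its sizes for genes not detected before RA, such as Hoxa5 and Igfbp5, therefore rest in part on values near background. By limma, 24 of 27 pluripotency genes fell over all genes and 26 when adjusted over the list alone, while 18 of 24 Hox genes rose (19, with 1 that fell, adjusted over the list alone). Of 19 retinoic acid response genes 13 rose and 1 fell (14 and 1 adjusted over the list alone), and of 14 imprinted genes 10 rose and 1 fell (10 and 1 adjusted over the list alone). Of 17 neural and neuronal genes 4 rose and 1 fell (4 and 1 adjusted over the list alone): Nkx6-1, Nes, Map2 and Dbx1 rose and Stmn2 fell.

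The same limma model gave, for extracellular matrix, 8 of 12 genes that rose and 1 that fell (8 and 1 adjusted over the list alone), and for endoderm 13 of 26 that rose and 4 that fell (15 and 5 adjusted over the list alone). Cell cycle genes had 0 that rose and 4 of 17 that fell (0 and 2 adjusted over the list alone), stress genes 0 and 4 of 10 (1 and 6 adjusted over the list alone), and interferon response genes 4 and 1 of 13 (7 and 1 adjusted over the list alone). For p53 targets 2 rose and 4 fell of 13 (3 and 5 adjusted over the list alone), for hypoxia 3 and 1 of 13 (2 and 0 adjusted over the list alone), for housekeeping 2 and 2 of 13 (2 and 3 adjusted over the list alone), and for MLL/SET1 complexes 1 and 3 of 11 (1 and 3 adjusted over the list alone). Of 11 mesoderm, endothelium and muscle genes 3 rose and 2 fell (3 and 2 adjusted over the list alone), of 7 trophectoderm genes 1 and 1 (2 and 3 adjusted over the list alone), of 7 germ line genes 0 and 1 (0 and 1 adjusted over the list alone), and of 6 fibroblast genes 2 and 1 (3 and 1 adjusted over the list alone).

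The RA effects in the 2 populations, which share no array, had Pearson's r of 0.873 and Spearman's rho of 0.829 across 9956 genes. Of 9234 genes compared in both, 1340 were higher in scramble cells and 1178 in knockdown cells, and 912 in both, where independent lists of these sizes would share 171. Likewise 1132 and 946 genes were lower, and 740 were lower in both, where independent lists would share 116.

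In undifferentiated cells the knockdown gave few differences of 2-fold. Of 8803 genes compared, 6 were higher and 11 lower by at least 2-fold, and 0 reached 4-fold. The higher genes were the actin regulator gene Pfn2 (2.41-fold), the histone genes H2bc4 (2.37-fold) and H1f2 (2.31-fold), Sp5, a transcription factor gene induced by Wnt signalling (2.35-fold), the muscle actin gene Acta1 (2.22-fold) and the transcription factor gene Atf5 (2.04-fold). Next in order, Spink1 (1.97-fold) and the imprinted H19 (1.95-fold) stayed below 2-fold. The largest decreases were in Sh3bgrl2 (2.70-fold), the tetraspanin gene Tspan8 (at least 2.64-fold), Lrrfip1 (2.56-fold), the kallikrein genes Klk1 (2.46-fold) and Klk1b5 (at least 2.29-fold), the protein kinase gene Prkx (2.43-fold), Akap8 itself (2.28-fold) and Paqr9 (at least 2.17-fold).

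No fixed list other than the targeted gene and extracellular matrix had a member past 2-fold in undifferentiated knockdown cells. Pluripotency genes had a median of 0.07 over 27 members, which ranged from -0.99 to 0.46, with Pou5f1 at 0.02 and Nanog at 0.05. The extracellular matrix list had a median of -0.48 over 7 members, below all 10000 random lists, with the fibulin gene Fbln2 at -1.06. The median was 0.34 for 6 interferon response genes, above 9987 of 10000 random lists, and -0.19 for 12 hypoxia genes, below 9997. It was 0.18 for 9 retinoic acid response genes, above 9871 random lists. Medians were 0.07 for 13 imprinted genes, 0.09 for 9 stress genes, 0.09 for 5 Hox genes and 0.24 for 3 fibroblast genes. They were within 0.1 of 0, with a sign that turned under at least 1 setting, for neural and neuronal (0.07, and -0.11 with the mean of probes), MLL/SET1 complexes (0.02), cell cycle (0.03), p53 targets (0.04), housekeeping (-0.02), endoderm (0.00) and germ line (0.05). The mesoderm and trophectoderm medians were 0.06 and 0.09. Of 15 named genes past 2-fold, all but Sh3bgrl2 and H1f2 were below it under at least 1 alternative setting of the values or probes, with Fbln2 at -0.06, Lrrfip1 at -0.41 and Klk1b5 at -0.07 with the mean of all probes and Paqr9 at -0.09 with median scaling. The counts were 3 higher and 3 lower without background correction or with an offset of 50, and 20 higher and 24 lower without bounds.

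After RA, the knockdown cells differed from scramble cells by at least 2-fold in 298 genes that were higher and 306 that were lower, of 9473 compared. With bounds taken at their value, the largest difference was in a gene that was lower, Sst (17.5-fold). The homeobox gene Msx1 was 10.9-fold lower, the FGF-binding gene Fgfbp3 10.4-fold and Ednrb, an endothelin receptor gene needed in the neural crest, 9.01-fold. The patterning gene Hoxd3 was 8.99-fold lower, and the neural genes Nefm, Dbx1 and Zic1 were 9.98-fold, 8.73-fold and 8.30-fold lower. The largest increases were in the prolactin family hormone genes Prl2b1 (at least 11.4-fold) and Prl3b1 (at least 10.2-fold), the placental cathepsin genes Ctsj (9.49-fold) and Ctsq (7.69-fold), Tuba3a, a tubulin gene of the testis (9.59-fold), the dipeptidase gene Dpep3 (at least 8.02-fold), Dazl, a germ cell RNA-binding protein (7.74-fold), and Rhox10, of the X-linked reproductive homeobox cluster (6.91-fold).

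Of 24 pluripotency genes compared after RA, 14 were higher in knockdown cells and 0 lower by at least 2-fold, with a median of 1.41, above all 10000 random lists. Members detected on neither RA-treated array were left out, so genes lost in both populations do not enter this median. Over 27 members, the RA effect in knockdown cells less that in scramble cells had a median of 0.94. Dppa4 was 5.75-fold higher, with a signal of 3016 in RA-treated knockdown and 627 in RA-treated scramble cells, and 7627 and 8359 in undifferentiated scramble and knockdown cells. The naive pluripotency gene Klf2 was higher by 2.38 on the log2 scale, and the Nodal antagonist genes Lefty2 and Lefty1 by at least 2.32 and by 2.22. Pou5f1 (3.15-fold), Nanog (3.14-fold), Esrrb (2.83-fold) and Zfp42 (2.81-fold) were also higher, while the log2 difference was 0.32 for Utf1, -0.11 for Sox2 and -0.45 for Lin28a. The germ line list had 4 of 7 members higher and 0 lower (median 1.54, above all 10000 random lists): Dazl, Taf7l (2.12), Stk31 (1.73) and Piwil2 (1.54). With a share of 4.06% of the undifferentiated knockdown signal subtracted from the RA-treated knockdown array, an alternative chosen after seeing the data, the pluripotency median was 0.31 and the germ line median 1.41. The share was taken from 48 genes lowered at least 16-fold by RA in scramble cells, of which 16 are of the pluripotency list. The move of the pluripotency median towards 0 therefore follows from the construction.

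Of 16 neural and neuronal genes compared after RA, 11 were lower in knockdown cells and 0 higher, with a median of -1.69, below all 10000 random lists. Besides Nefm, Dbx1 and Zic1 they included Stmn2 (6.42-fold lower), the growth cone gene Gap43 (-2.46) and Dcx (-2.44). Of 19 retinoic acid response genes, 5 were lower and 1 higher (median -0.54, below all 10000 random lists). The retinoid-binding protein genes Crabp1 and Crabp2 were 5.64-fold and 3.35-fold lower and Aldh1a2, a gene of RA synthesis, at least 2.33-fold lower, while Stra8 was 5.27-fold higher. Of 23 Hox genes 4 were lower and 0 higher: Hoxd3, Hoxd4 (7.57-fold), Hoxc6 (2.97-fold) and Hoxb6 (2.86-fold). Hoxa5 was at -0.05 and Hoxb1 at 0.89 (median of the list -0.22). Of 12 extracellular matrix genes 5 were lower and 0 higher (median -0.75, below all 10000 random lists), among them Fbln2 (-1.71), the collagen genes Col1a1 (-1.67) and Col6a1 (-1.11), and the collagenase gene Mmp2 (-1.22). Of 14 imprinted genes Mest was lower (-1.26) and Phlda2 higher (1.34), with a median of -0.28.

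Markers of other cell types also differed after RA. Fibroblast markers had 3 of 5 lower and 0 higher (median -1.04), with Vim at -1.30 and Col3a1 at -1.04, a bound. Of 24 endoderm markers 4 were lower and 0 higher (median -0.21): Cxcr4 (-1.79), Pth1r (-1.76), Gata6 (-1.31) and Sox17 (-1.09). Of 11 mesoderm markers the muscle actin gene Actc1 was lower (-1.23) and Pecam1 higher (1.22; median -0.23). Trophectoderm had 2 of 5 higher and 0 lower (median 0.60), Plac1 (3.02-fold) and Tfap2c (2.58-fold). The interferon response list had 2 of 12 higher and 0 lower (Oasl2 1.81, Rsad2 1.29), with a median of 0.53, above all 10000 random lists. Vegfa (-1.05) was the member past 2-fold of 13 hypoxia genes (median -0.38, below 9995 of 10000 random lists). The mitotic kinase gene Aurka (-1.13) was that of 17 cell cycle genes (median 0.08, with a sign that turned with the mean of probes). No member passed 2-fold in p53 targets (median 0.15), stress genes (0.13), MLL/SET1 complexes (0.16) or housekeeping genes (-0.01). Of 51 named genes past 2-fold, 11 were below it under at least 1 alternative setting of the values or probes: Aldh1a2, Aurka, Rsad2, Vegfa, Fbln2 (-0.87 with the mean of all probes), Col6a1, Sox17, Actc1, Pecam1, Stk31 (0.88 with the mean of all probes) and Col3a1 (-0.30 with the mean of all probes). Without background correction 153 genes were higher and 170 lower (neural and fibroblast medians -1.08 and -0.65), with the deposited median-normalized values 187 and 157 (-1.11 and -0.60), and with an offset of 50 the counts were 188 and 183.

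**Figure D2:**
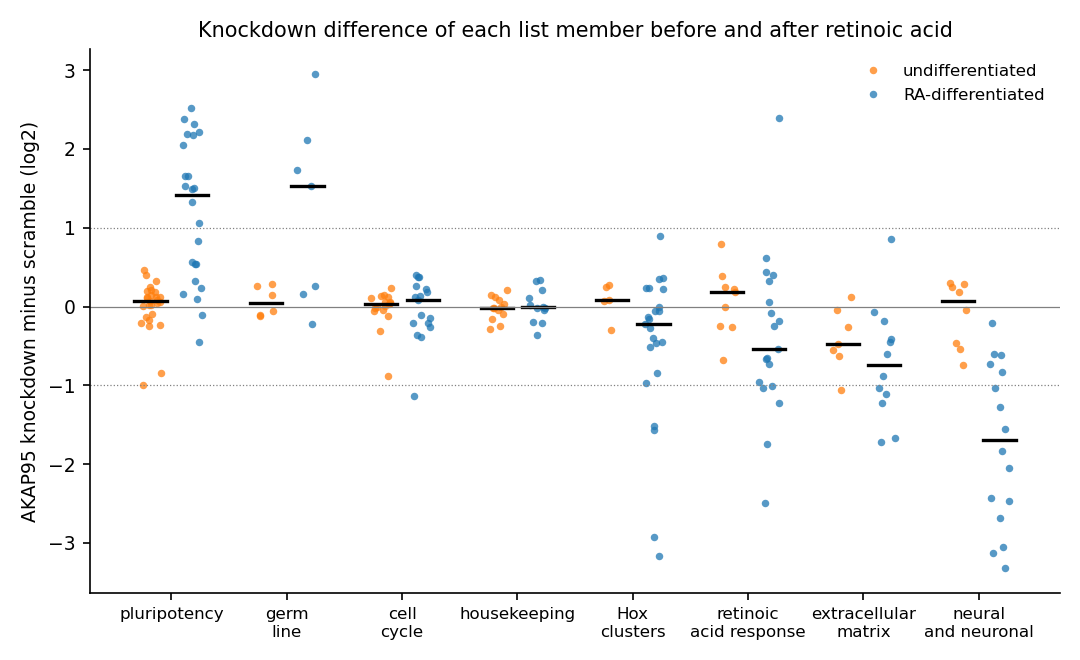
Each point is a list member and shows its log2 difference of AKAP95 knockdown minus scramble cells, in undifferentiated cells (orange) and after RA (blue); black bars are list medians, and dotted lines mark a 2-fold difference. The pluripotency median is 0.07 before and 1.41 after RA, and the neural and neuronal median 0.07 before, with a sign that turns with the mean of probes, and -1.69 after.

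Over both states, limma found 0 genes with a knockdown effect at an adjusted p under 0.05, against 416 at an unadjusted p under 0.05, of which 174 were higher and 242 lower. The smallest adjusted p from limma was 0.817, at which stood the histone gene H1f2 (1.28), Acta1 (1.39), Sfn (0.97), Tinagl1 (1.02) and Plekha4 (0.84), all higher, and the proteoglycan gene Ncan (-1.55), Lrrfip1 (-1.20), Tspan2 (-1.30), Fbln2 (-1.39) and the chromatin organizer gene Satb1 (-1.01), all lower. Adjusted over the list alone, no list but that of the targeted gene had a member under 0.05. The model had little power for a gene that the knockdown changed after RA alone. The crossed contrast of such a gene is as large as its knockdown contrast, and the model takes it as error. These limma results therefore do not show that the knockdown was without effect after RA. The knockdown effects before and after RA, which share no array, had Pearson's r of 0.142 and Spearman's rho of 0.140 across 9956 genes. Of 8320 genes compared in both states 2 were higher in both and 2 lower in both, where independent lists would share 0.198 and 0.156. Few genes enter these counts, and some depend on the setting. In undifferentiated cells, Lrrfip1 and Fbln2 were at -0.41 and -0.06 with the mean of all probes. Acta1 was at 0.93 there without background correction, while H1f2 stayed past 2-fold under each alternative setting of the values or probes. Of the 9956 genes, 2202 had an RA contrast of at least 1 in size, 127 a knockdown contrast and 88 the crossed contrast, which holds noise and any interaction alone.

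The genes that differed between the populations after RA were for the most part genes that RA moved in scramble cells. Of all 9584 genes compared there, 1136 were lower and 1361 higher by at least 2-fold. Of the 298 genes higher in knockdown cells, 183 (61.4%) were lower by at least 2-fold after RA in scramble cells and 12 (4.03%) higher. Of the 306 genes lower in knockdown cells, 223 (72.9%) were higher after RA in scramble cells and 3 (0.980%) lower. These pairs of differences share the RA-treated scramble array, so noise in it alone gives some of this overlap. Genes chosen on the mean RA effect of both populations avoid this. For 1227 RA-induced genes the median RA effect was 1.62 in scramble and 1.41 in knockdown cells, with a median difference of -0.23, and 819 (66.7%) had the smaller effect in knockdown cells. For 975 RA-repressed genes the medians were -1.58 and -1.40, with a median difference of 0.19, and 612 (62.8%) had the smaller effect in knockdown cells. With genes chosen on the knockdown arrays alone the median differences were -0.028 and -0.022, so that the second turned its sign.

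The genes whose RA effect was furthest above that of scramble cells were Tuba3a (difference of the log2 effects 3.61), Prl2b1, Prl3b1, Tex19.2, a germ line gene (3.34), and Lefty1 (3.20). Prl2b1 and Prl3b1 were detected on the RA-treated knockdown array alone, so no size is given for them. Those furthest below were Sst (-4.13), Msx1 (-3.71), Fgfbp3 (-3.64), Nefm (-3.32) and Ednrb (-3.17). Of these, Sst, Nefm and Ednrb were not detected on either undifferentiated array. Their levels there were set to the lowest detected values, 5.51 on both arrays, so their differences restate the knockdown difference after RA. The same holds for list members that were raised to these values on both arrays. Of the neural and neuronal list, 8 members were detected on at least 1 undifferentiated array. The pluripotency list had 13 of 27 members with a difference of at least 1 and 0 of -1 or less (median 0.94), and the neural and neuronal list 0 and 11 of 17 (median -1.55). No test of these differences could be made, because the additive model uses its 1 residual degree of freedom for them.

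**Figure D3:**
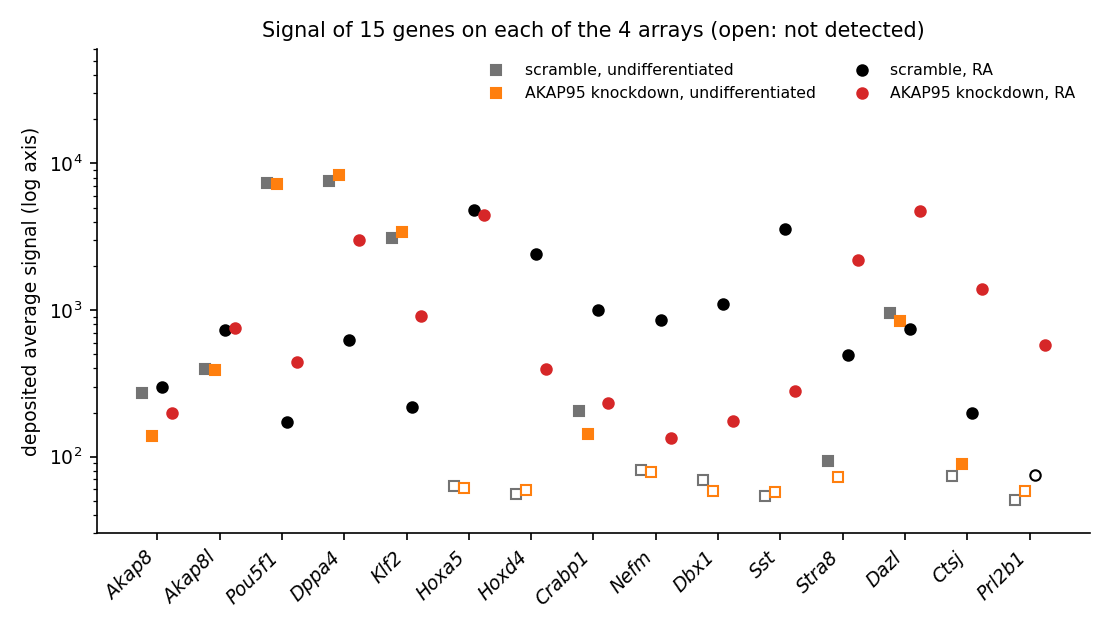
Points show the deposited average signal, on a logarithmic axis, of Akap8, its paralog and genes of the RA response, pluripotency, neural, germ line and placental groups on each array, with open symbols where the gene was not detected. Akap8 is at 272 and 139 in undifferentiated and at 297 and 199.7 in RA-treated scramble and knockdown cells, and Dppa4 is at 627 and 3016 in RA-treated scramble and knockdown cells.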

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

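Of the tests in this part, those of the share that induced genes would need, of an equal residual share, of that share as the whole cause, of levels outside the range and of a deeper Akap8 knockdown were chosen only after the result was seen.

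Sp5, a transcription factor gene induced by Wnt signalling, moved in opposite directions in the 2 cell populations. Its log2 difference with RA was 1.97 in scramble cells and -1.03 in knockdown cells, and its knockdown difference was 1.23 in undifferentiated cells and -1.76 after RA. The difference was not tested. Of these, -1.03 fell under 2-fold in all 5 other settings (-0.75 without background correction, -0.51 with the deposited values), and 1.23 fell under it in 3 (0.88 without background correction, 0.81 with the deposited values, 0.94 with an offset of 50), with every sign kept. For the RA effects, 6 genes were past 2-fold in opposite directions in the 2 populations (1 to 6 over the settings), and for the knockdown effects this was 1 gene (0 to 2).

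Pluripotency genes were higher in RA-treated knockdown cells than in RA-treated scramble cells (median 1.41), and scaling or background correction was argued against, since the median over members lowered by RA was at least 1.07 under each of 6 value settings. A share of undifferentiated cells left in the RA-treated knockdown culture would give each strongly lowered gene an equal share of its undifferentiated level. This takes leftover cells to have kept the profile of the undifferentiated knockdown culture, which was not tested. The median share was 4.06% over 48 genes lowered at least 16-fold by RA in scramble cells. They were chosen on the RA-treated scramble array, which also enters the share, so noise in that array bears on it. Of these genes, 58.3% lay within 2-fold of the median share. That is too few for an equal share and too many to exclude one. Leftover cells and a slower loss of these genes therefore cannot be told apart. Levels scattered around 1 such share with a robust SD of 0.516 on the log2 scale, with Klf2 at 19.4% and Utf1 at 0.763%, against 0.186 between probes of the same gene, and whether that excludes it as the whole cause stays open, since the latter does not hold the spread between cultures. A biological difference from the loss of AKAP95 stays open and untested, with 1 array per group.

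RA-induced genes were lower in RA-treated knockdown than in RA-treated scramble cells, with a median over genes induced on the mean of both populations of -0.23. Under each of 6 value settings that median was -0.177 or lower, which argues against the scaling of the arrays. For this choice of genes it argues as well against leftover cells as the whole cause, if they kept the profile of the undifferentiated knockdown culture. A median of -0.177 would need a share of 11.5%, which 3 of the 48 strongly lowered genes reached. The limit for an induced gene at the median share of 4.06% is -0.060. Both the share and this limit rest on genes chosen in scramble cells alone. With genes chosen in scramble cells alone the median was -0.34, and with genes chosen in knockdown cells alone -0.059, within that limit, and whether noise or real differences in response move the median between these choices was not tested. A weaker response of the knockdown cells, a culture that was less far along, or a difference between cultures unrelated to the shRNA stay open, since the 1 RA-treated culture of each kind confounds them.

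Far more genes differed between knockdown and scramble cells after RA (298 higher, 306 lower) than before (6 and 11). Probe noise was argued against, since pairs of probes of 1 gene had Pearson's r of 0.838 across genes for the difference after RA. A deeper knockdown of the Akap8 transcript after RA was argued against. Under each of 6 value settings its log2 difference was closer to 0 after RA, by at least 0.328. That rests on 1 probe, and AKAP95 protein was not measured on these arrays. Leftover cells with the profile of the undifferentiated knockdown culture were argued against as the whole cause. Under each of the 6 value settings, at least 14.6% of the genes past 2-fold lay outside a range by at least 2-fold in RA-treated knockdown cells. That range ran between RA-treated scramble and undifferentiated knockdown cells, and Prl2b1, Ctsj, Dazl and Stra8 lay outside it. Leftover cells that the RA culture had changed need not lie within it, and were not tested. A state-dependent effect of the AKAP95 shRNA, through loss of AKAP95 or otherwise, may underlie the pattern. So may a difference between RA-treated cultures, since the design has 1 of each.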

How the results depend on the processing

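The subtraction of an undifferentiated share was chosen after seeing the data and the other alternatives before. No paired analysis was possible because each group has 1 array, beyond the additive limma model, which takes the RA effect within each cell population. Signal over background limits the values: of 9584 genes compared between scramble arrays 1727 rest on a bound, and where a gene is near the detection limit its difference depends on the background correction. limma found 0 genes with a knockdown effect under each alternative fit, and between 1481 and 2568 that rose and between 1431 and 1919 that fell with RA. As in the main fit, each of them takes a knockdown effect present after RA alone in part as error. For all values below the cause was not tested, except where a stricter size rule or filter leaves fewer genes by construction or where it is stated. Of the values for the named genes, 546 moved by more than the spread between probes of 1 gene and 861 did not, and of the list medians beside the main ones 19 moved and 319 did not.

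With a 3-fold rule, RA gave 665 genes higher and 497 lower in scramble cells and 487 and 385 in knockdown cells, and the knockdown gave 0 and 0 in undifferentiated cells and 93 and 90 after RA. Without background correction, 627 genes were lower with RA in knockdown cells, the knockdown counts were 3 and 3 before and 153 and 170 after RA, and 39 genes had a crossed and 55 a knockdown contrast of at least 1. Akap8 was at -0.93 and -0.60, the neural median at 0.99 for RA in scramble cells and -1.08 for the knockdown after RA, the endoderm median at 0.84 for RA in scramble cells, and the germ line and fibroblast medians after RA at 1.01 and -0.65. With the deposited median-normalized values, 699 and 474 genes were lower with RA in scramble and knockdown cells, the knockdown counts were 3 and 4 before and 187 and 157 after RA, and 38 genes had a crossed and 51 a knockdown contrast of at least 1. The median difference for RA-repressed genes was then 0.29, Akap8 was at -0.96 and -0.56, and the neural and fibroblast medians after RA were -1.11 and -0.60. With an offset of 50, the knockdown counts were 3 and 3 before and 188 and 183 after RA, 41 genes had a crossed and 59 a knockdown contrast of at least 1, Akap8 in undifferentiated cells was at -0.98, and the fibroblast median after RA was -0.67.

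With a detection p under 0.05, 10 genes were higher in undifferentiated knockdown cells, and without bounds 20 were higher and 24 lower. With the mean of all probes, 7 genes were lower there, and medians were 1.79 for Hox genes and 0.44 for extracellular matrix with RA in knockdown cells, 0.88 for neural genes and 0.86 for endoderm with RA in scramble cells, and -1.11 for neural genes, 0.88 for germ line and -0.53 for fibroblast for the knockdown after RA. With detection on every array compared, 7 genes were lower in undifferentiated knockdown cells, and 46 had a crossed and 84 a knockdown contrast of at least 1. With genes chosen in scramble cells alone, the RA response of induced and repressed genes differed by -0.37 and 0.34, and with genes chosen in knockdown cells alone by -0.028 and -0.022, the second with its sign turned. With the undifferentiated share subtracted, the pluripotency median after RA was 0.31, which follows from the construction, since 16 of the 48 genes that gave the share are of that list. The other values that answer a comparison stayed within 1.5-fold of the main ones, or within the spread between probes of 1 gene, under all alternatives run.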

Other observations

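All of the families described here were chosen after the values were seen.

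After RA, members of several families were higher in knockdown than in scramble cells. Stra8, 1 of them, is also a member of the fixed retinoic acid response list. A gene detected on the RA-treated knockdown array alone enters such a count and cannot be lower. Of 16 genes of the Rhox cluster on the arrays, X-linked homeobox genes of reproductive tissues and placenta, 9 were compared and 5 were higher by at least 2-fold: Rhox10 (2.79), Rhox5 (2.71), Rhox4d (2.57), Rhox9 (2.56) and Rhox6 (2.55). Of 12 meiosis genes on the arrays 5 were compared and 4 were higher, the cohesin genes Smc1b (2.43) and Rec8 (1.64), Stra8 (2.40) and Hormad2 (at least 1.09), while Syce2 was at 0.10, and 3 were higher without background correction, with the deposited median-normalized values or with an offset of 50. Of 22 prolactin family genes on the arrays 5 were detected, all on the RA-treated knockdown array alone, and 3 of these were at least 2-fold higher (2 under the same alternatives). Of 8 placental cathepsin genes 3 were compared and 2 were higher (Ctsj and Ctsq). Of 9 guanylate-binding protein genes, which interferon induces, 4 were compared and 3 were higher (Gbp2b 2.10, Gbp3 2.07, Gbp2 1.86). Members of these families resemble each other in sequence, and signal shared between their probes was not examined.

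Among 4 genes of DNA methylation, Dnmt3l was higher after RA in knockdown than in scramble cells by at least 2.48, while the maintenance enzyme gene Dnmt1 (0.14), its partner Uhrf1 (0.00) and the de novo enzyme gene Dnmt3b (0.11) were within 0.2 of 0. With RA, Dnmt3b was at -2.17 in scramble and -1.75 in knockdown cells. The histone group was picked by a pattern of symbols that also takes in H19, an imprinted gene and not a histone gene. Its counts and medians may therefore hold such genes. Of 45 genes of the group compared, 12 were lower and 2 higher by at least 2-fold after RA in scramble cells. Of 44 in knockdown cells, 22 were lower and 1 higher. The counts of lower genes were 4 and 15 with the deposited median-normalized values and 7 and 17 without background correction. The knockdown difference after RA had a median of -0.33 over 42 genes of the group, and of -0.21 with the deposited values.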
